A study of Mus musculus with 8 samples.

How the data were processed

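The series holds 8 libraries from C57BL/6 mice aged 8 to 12 weeks. There were 3 H3K9me2 CUT&RUN libraries of tumour Treg with a Treg-specific conditional knockout of Jmjd1c (cKO), 3 of WT tumour Treg, and 1 ATAC-seq library each of tumour Treg and spleen Treg. Per the labels' protocols, Treg were enriched on magnetic beads and sorted by fluorescence, and the ATAC libraries were prepared by a service company. Groups and replicate numbers were taken from the titles. The submitters' processing notes name Trim Galore 0.6.6, Bowtie2 2.4.2, Picard, SAMtools 1.11, HOMER and deepTools and the build mm10, with no role given for each. Whether ATAC reads were shifted for the transposase is not given in the sources used here.

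Per the file headers, the authors called peaks with HOMER findPeaks in each library alone, without an input or control library and without pooling replicates. H3K9me2 was called in histone style with a peak size of 500 bp and a tag threshold of 5, where 6.49 to 7.81 tags per peak were the expectation in a library. Peaks were filtered against the surrounding 10 kb by a Poisson p of 0.05. The fold required over that region was set lower in the call of cKO replicate 3 than in the other 5, at values so small that the headers print 0 for all 6. ATAC peaks were called in factor style, with a peak width of 322 bp in tumour and 869 bp in spleen estimated by the caller. Per the file headers, the tag signal of a peak is scaled to a common library total, the score of a peak is in tags of its own library, and the fold over the surrounding region and its p-value come from the caller. The deposited ATAC files also give a focus ratio, a fraction of tags placed in a focused peak, and the deposited H3K9me2 files give the size of each region in bp (other unit). These scores and folds are the authors' own values per peak and were used only to rank or filter peaks within a list.

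The deposited H3K9me2 lists were shorter than the number of peaks in their own headers, holding 24.4 to 43.9% of it. Every deposited H3K9me2 peak had a fold over the local region of 2.01 or more, a p-value of 0.0496 or less and a clonal fold of 1 or less, so a further filter was applied after calling that no header states. Both steps select short stretches that stand out from their neighbourhood. The covered length therefore measures local enrichment of H3K9me2 and not its amount, and a broad, even domain can be missed. Since the scale of the scores is set within each library, a change in the total level of the mark between cKO and WT cannot be measured from these values. Genes and windows with few peaks may be limited by depth, which was not tested. It was 24774509 to 30313851 tags per H3K9me2 library and 11068821 (spleen) and 11293674 (tumour) tags per ATAC library. The headers give 29.57 to 35.26% of tags in the called H3K9me2 peaks.

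From these lists, peaks on the autosomes, X and Y were merged within each library, and the percent of each region covered by peaks was computed. Shares of the genome refer to 2722.4 Mb with Y. Windows and the genome-wide coverage used for scaling left Y out. Gene positions came from a RefSeq gene table of the same build with 21887 protein-coding genes. The table used gives no strand, so the planned region from 5 kb upstream to the gene end was replaced by the gene span with 5 kb on both sides, and the planned windows around transcription start sites were not run. Genes with a mean under 1% over the 6 libraries were not tested. Covered percents were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 18 lists. The lists were H3K9 methylation machinery, Treg identity, tumour and effector Treg, inhibitory receptors and PD-1 control, JAK-STAT3, PI3K-AKT-mTOR, Th1 and interferon-gamma, naive and lymphoid homing, CD8 T and NK cell, B cell, myeloid cell, melanocyte and epithelial, stromal and endothelial and ubiquitous genes, and the olfactory receptor, vomeronasal receptor, zinc-finger and clustered protocadherin families. These lists, the tests of genes and 1 kb windows, and most alternatives were chosen before the data were examined. The 1 Mb windows, the gene-density classes and the X to autosome ratio were added afterwards. For 1 Mb windows the covered percent was divided by that of the whole genome in the same library, and windows with a mean of 1% or more were tested.

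On simulated data made from the same libraries, with 200 of 19018 genes changed, limma recovered 37% of shifts of 10 percentage points and 95% of shifts of 20, with 7 false calls. With 200 of 2552 windows changed, it recovered 8% of shifts of 0.3 and 76% of shifts of 0.6 times the genome-wide coverage, with 1 false call. Noise was drawn from a normal distribution independently for each gene or window, and values below 0 were set to 0. These rates need not hold in the real data. Single values per library were compared by exact permutation tests, two-sided, whose 10 splits of 3 against 3 allow no p below 0.1. Windows of 1 kb were counted as covered from 500 bp.

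The genes named in the text follow a rule set before the data were examined. It takes Jmjd1c, Pdcd1, Stat3, Foxp3 and Ifng, then the 10 genes with the largest rise and the 10 with the largest fall past the threshold, or by limma p among genes whose groups do not overlap where fewer pass. From each fixed list it takes up to 4 members by p, or by the difference in the number of peaks for ATAC. For ATAC it also takes the 10 genes with the most peaks found in tumour alone and in spleen alone. Genes without an assigned symbol were left out, except a single gene called on another scale, and 1 gene that the rule takes is not reported here. The 1 Mb windows and the list members within them were named after their values were seen.

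ATAC peaks were counted as shared from an overlap of 1 bp, with Wilson 95% intervals for shares, and assigned to genes extended by 5 kb or within 1 kb of either gene end. Lists were ranked by the share of members with a peak found in tumour alone among 10000 random lists of the same size, and a peak found in a single library means that no peak of the other touched it. A longer list takes in more of everything, so values were repeated with the tumour list shortened to the 13078 highest-scoring peaks. The H3K9me2 lists were likewise shortened to the 109589 peaks of the shortest. Other alternatives were the higher-scoring part of each list, each library left out, division by genome-wide coverage, other filters, other window sizes, an arcsine scale and the replicate number as a block. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures with matplotlib 3.10.9.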

Results

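Regulatory T cells (Treg), the Foxp3-expressing CD4 T cells that restrain immune responses, were sorted from tumours of C57BL/6 mice aged 8 to 12 weeks. Dimethylation of lysine 9 on histone H3 (H3K9me2), a mark of silent chromatin, was profiled by CUT&RUN, in which an antibody directs a nuclease to release the DNA that carries the mark. There were 3 libraries from wild-type (WT) mice and 3 from mice with a Treg-specific conditional knockout (cKO) of Jmjd1c, which encodes a member of a family of H3K9 demethylases. Accessible chromatin was profiled by ATAC-seq, in which a transposase tags open DNA, in 1 library of tumour Treg and 1 library of spleen Treg from WT mice. The H3K9me2 libraries held 24774509, 30313851 and 26526146 tags in cKO replicates 1 to 3 and 29229071, 28567199 and 29577405 in WT replicates 1 to 3, and the ATAC libraries held 11293674 tags for tumour and 11068821 for spleen. The deposited values were peak lists called separately in each library. H3K9me2 was therefore compared as the percent of a gene or window covered by peaks, given as mean ± SD with n = 3 in each group. Nothing in the labels says that the replicates came from separate animals, so the spread between these samples that enters the p-values may be technical. The sample names in the file headers give cKO replicates 1 and 3 the same knockout number, so these may share a source. The names carry 3 prefixes in cKO and 2 in WT with 0 in common, so any batch they stand for cannot be separated from genotype.

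Loss of Jmjd1c was compared with WT first at the scale of the whole genome. H3K9me2 peaks covered 118 ± 22.8 Mb in cKO Treg and 99.9 ± 9.50 Mb in WT Treg, or 4.34 ± 0.836% and 3.67 ± 0.349% of the genome. The difference of 18.1 Mb lay within the spread between libraries (exact permutation test, two-sided, p = 0.3, where 0.1 is the smallest p that 3 against 3 can give). It was 6.50 Mb without cKO replicate 1, the library with the most peaks, 29.3 Mb without cKO replicate 3, 3.598 Mb with lists of equal length and 9.77 Mb with the stronger 50% of each list. The number of peaks was 144492 ± 32317 in cKO and 123675 ± 13354 in WT (exact permutation p = 0.4). On the autosomes, X and Y the difference was 20777 peaks, and 3777 without cKO replicate 1, 35864.5 without cKO replicate 3 and 10388.7 with the stronger 50% of each list. Single peaks were short, with a median length of 628 to 635 bp, and were shared by few libraries. In each pair of libraries, 14.5 to 20.4% of the peaks of the first touched a peak of the second. The first was the cKO library, or the lower replicate number within a group. The share in the other direction was not computed. The overlap was 2.77 to 3.29 times the chance value for a cKO and a WT library, 2.98 to 3.09 times within cKO and 3.11 to 3.53 times within WT.

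At single genes the knockout and WT could not be told apart by the test that was run. Jmjd1c itself (chromosome 10, 67096351 to 67256326, mm10) was covered over 2.14, 3.26 and 1.78% of its span with 5 kb on each side in cKO replicates 1 to 3 and over 1.46, 2.16 and 1.47% in WT replicates 1 to 3. That coverage is a chromatin mark and does not show whether the gene was deleted. Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), had 2.48 ± 4.30% in cKO and 3.62 ± 1.37% in WT. Stat3, a transcription factor downstream of several cytokine receptors (chromosome 11, 100886806 to 100939594), had 2.39 ± 2.11% and 0.336 ± 0.582%. Foxp3, the lineage-defining factor of Treg (chromosome X, 7579676 to 7595243), had 10.02 ± 6.68% and 8.97 ± 0.718%. Ifng, which encodes interferon-gamma (chromosome 10, 118441046 to 118445894), had 12.9 ± 1.93% and 10.3 ± 5.11%. The limma p-values of Jmjd1c, Pdcd1, Stat3, Foxp3 and Ifng were 0.544, 0.624, 0.148, 0.777 and 0.491, and their adjusted p-values lay between 0.619 and 0.934.

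Of 19018 protein-coding genes tested with limma, 0 passed an adjusted p of 0.05, and the lowest adjusted p was 0.519. At an unadjusted p under 0.05 there were 1591 genes, 1412 with higher and 179 with lower coverage in cKO. With each library's coverage divided by its genome-wide coverage, 0 genes passed and 1273 had an unadjusted p under 0.05, of which 962 were higher and 311 lower. The median difference over all genes was 1.26 percentage points before this scaling and 0.175 after it, in units of the genome-wide coverage. On an arcsine square root scale 1 gene passed, the predicted gene Gm14444, with 29.5 ± 0.996% in cKO and 0% in each WT library (limma adjusted p = 0.00534 on that scale). The 3 libraries of each group did not overlap at 2474 genes with higher and 255 genes with lower coverage in cKO, 14.3% of all genes, where chance gives 10%. In simulated data the test recovered 37% of genes shifted by 10 percentage points and 95% of those shifted by 20. Simulated noise was normal and independent between genes, and values were cut at 0. The median estimated shifts were 8.26 and 14.2 percentage points. On the percent scale, real genes with differences of that size passed no threshold, such as Srsx with 15.3% in cKO and 0% in WT (limma adjusted p = 0.519). The recovered shares therefore need not hold for the real genes.

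The genes with the smallest limma p among those whose groups did not overlap passed no threshold (adjusted p = 0.519 for each) and were mostly covered in one group and free of peaks in the other. In short genes a single peak covers several percent of the extended span. The values of such genes, here and in the lists below, can therefore rest on a single peak per library. Higher in cKO and at 0 in each WT library were Srsx (15.3 ± 2.57%), Nupr1l (10.7 ± 0.506%), the olfactory receptor genes Olfr1359 (11.1 ± 1.71%) and Olfr1046 (9.92 ± 2.398%), Hrc, which encodes a histidine-rich calcium-binding protein (9.07 ± 0.811%), Scgb1b29 (11.5 ± 2.34%), Ajm1 (9.30 ± 1.114%), Prr19 (10.1 ± 1.92%) and the cytokine gene Il1f10 (9.03 ± 1.45%). The homeobox gene Barhl1 had 11.1 ± 0.669% in cKO and 0.822 ± 1.42% in WT. Lower in cKO, and at 0 in each cKO library, were Olfr960 (11.7 ± 1.65% in WT), Klhl34 (13.0 ± 3.33%), Mycs (12.2 ± 4.16%), Sdr42e1 (14.2 ± 5.18%), Olfr1008 (10.6 ± 3.71%), Igfl3 (7.67 ± 1.98%) and the lipase gene Cel (5.81 ± 0.342%). The neuropeptide gene Cartpt had 1.23 ± 1.59% in cKO and 11.9 ± 1.69% in WT, Olfr1101 had 2.33 ± 4.04% and 16.5 ± 0.778%, and the cytochrome c oxidase subunit gene Cox8c had 2.54 ± 2.29% and 20.6 ± 5.97%.

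Gene lists fixed in advance were compared with all other genes. Most tested genes were higher in cKO, as their median difference was 1.26 percentage points. The counts of higher members given here and below are therefore not by themselves particular to a list. Inhibitory receptors and regulators of PD-1 had the largest mean excess of coverage in cKO among the 18 lists, 5.02 ± 0.758% against 2.55 ± 0.761%, although 3 lists had a larger median difference over their genes, with 16 of 17 tested members higher in cKO. This list had a camera p of 0.0291 and an adjusted p of 0.175, and p = 0.313 with an estimated correlation. Its members with the smallest limma p were Btla, an inhibitory receptor of lymphocytes, with 9.03 ± 3.95% in cKO and 1.99 ± 0.952% in WT (limma adjusted p = 0.540), Havcr2, which encodes TIM-3, with 7.45 ± 4.57% and 1.66 ± 1.46% (limma adjusted p = 0.568), Cd200r1 (9.31 ± 4.63% and 3.05 ± 2.66%) and Cd160 (8.30 ± 0.682% and 4.14 ± 2.57%). Treg identity genes had 4.34 ± 0.604% and 2.56 ± 1.18%, with 17 of 18 tested members higher in cKO (camera adjusted p = 0.551). They were led by Nt5e, which encodes the ectonucleotidase CD73, with 4.59 ± 0.503% and 0.613 ± 0.531% (limma adjusted p = 0.519), and Rtkn2 with 7.18 ± 1.36% and 1.95 ± 1.21% (limma adjusted p = 0.519), followed by Entpd1 (CD39) and Swap70. Genes of tumour and effector Treg had 4.49 ± 1.17% and 2.59 ± 0.721%, with 20 of 25 tested members higher (camera adjusted p = 0.675). Areg, which encodes the growth factor amphiregulin, had 0% in each cKO library and 3.86 ± 1.35% in WT (limma adjusted p = 0.519), a value that a single peak per library can give. Hopx had 7.60 ± 4.05% in cKO and 1.31 ± 1.31% in WT, Prdm1, which encodes Blimp-1, 7.26 ± 2.11% and 2.33 ± 1.66%, and Layn 7.55 ± 2.87% and 2.90 ± 0.361%.

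Signalling and differentiation lists did not separate from other genes either. PI3K-AKT-mTOR signalling had 4.04 ± 0.797% in cKO and 2.46 ± 0.965% in WT, with 20 of 23 members higher (camera adjusted p = 0.551), led by Tsc2, an inhibitor of mTORC1, with 3.66 ± 1.27% and 0% (limma adjusted p = 0.530). JAK-STAT3 signalling had 3.35 ± 1.28% and 2.16 ± 1.62% (camera adjusted p = 0.709), with Il23r, the interleukin-23 receptor gene, at 10.1 ± 2.57% and 4.91 ± 0.713%. Th1 and interferon-gamma genes had 4.68 ± 1.49% and 3.49 ± 1.46% (camera adjusted p = 0.709), with the interleukin-12 receptor gene Il12rb2 at 5.79 ± 1.17% and 1.97 ± 0.459% and Nkg7 at 8.28 ± 2.46% and 3.01 ± 2.60%. Naive and lymphoid homing genes had 4.18 ± 0.706% and 2.53 ± 1.05% (camera adjusted p = 0.675), with S1pr1, the receptor that guides exit from lymphoid organs, at 9.18 ± 2.62% and 2.28 ± 1.98% (limma adjusted p = 0.519). H3K9 methylation machinery had 3.69 ± 0.513% and 2.67 ± 0.379% (camera adjusted p = 0.675), with the H3K9 methyltransferase gene Setdb1 at 3.43 ± 0.164% and 0.382 ± 0.662% (limma adjusted p = 0.556) and the demethylase genes Kdm3a, Kdm1a and Kdm4a not overlapping between the groups. Zinc-finger genes had 6.08 ± 0.945% and 4.46 ± 0.524%, with 268 of 371 tested members higher in cKO (camera adjusted p = 0.675), and clustered protocadherins had 4.61 ± 1.99% and 3.83 ± 0.1798% (camera adjusted p = 0.675).

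Lists for other cell types did not separate from other genes. CD8 T and NK cell genes had 6.39 ± 2.97% in cKO and 4.44 ± 0.698% in WT, and B cell genes 4.93 ± 2.49% and 3.40 ± 0.0918%. Myeloid genes had 4.67 ± 1.21% and 3.64 ± 0.193%, melanocyte and epithelial genes 4.44 ± 0.488% and 4.15 ± 1.49%, stromal and endothelial genes 4.08 ± 0.702% and 3.56 ± 0.418%, and ubiquitous genes 3.13 ± 0.832% and 2.43 ± 1.47%. The lowest camera adjusted p of these was 0.675. Among myeloid genes, S100a9, a subunit of calprotectin, had 0% in cKO and 7.62 ± 3.58% in WT (limma adjusted p = 0.519), and Spi1, which encodes the transcription factor PU.1, had 4.90 ± 1.04% and 0.770 ± 1.33% (limma adjusted p = 0.548). In each of the 18 lists, 0 members passed over all genes tested and 0 passed adjusted over the list alone.

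Both lists that passed were families of chemosensory receptors in gene clusters. Olfactory receptor genes (770 tested) and vomeronasal receptor genes (215 tested) fell relative to other genes with a camera adjusted p of 0.00128 for each. With an estimated correlation the p-values were 0.106 and 0.0630, and the adjusted p was 0.888 for both, so neither call held. The direction is relative, since their own median differences were positive, 0.832 and 0.0715 percentage points, and so were their means, 4.79 ± 1.38% in cKO against 4.20 ± 0.700% in WT and 4.90 ± 1.12% against 4.83 ± 0.435%. Neither passed with peak lists of equal length, without cKO replicate 2 or without WT replicate 1. The camera direction also differed from the sign of the mean and median difference in Th1, melanocyte and epithelial, stromal and endothelial, ubiquitous and protocadherin genes, which were ranked below other genes with positive differences. H3K9 methylation, JAK-STAT3 and myeloid genes were ranked above other genes although their mean differences minus that of all genes were -0.232, -0.0569 and -0.219 percentage points.

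Regions that separated the groups were sought in 2631592 windows of 1 kb. There were 1530 windows covered over 500 bp or more in all 3 cKO libraries and in 0 of 3 WT libraries, and 985 windows with the reverse pattern. The other splits of the 6 libraries gave between 2024 and 2283 such windows in total, against 2515 for the real split, although another split had more windows on a single side, 1712. In all 6 libraries, 183 windows were covered. With windows of 5 kb the counts were 6 and 7, and their total of 13 lay within the 8 to 16 of the other splits. With peak lists of equal length the counts were 926 and 985. Leaving out 1 library loosens the requirement on its group and gave 1875 to 10213 cKO windows and 1227 to 6670 WT windows.

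At the scale of 1 Mb, a comparison added after the data were seen, relative coverage moved from gene-poor towards gene-rich sequence in cKO Treg. Relative to the genome-wide coverage of each library, 97 of 2552 windows rose and 275 fell in cKO (limma, adjusted p under 0.05), and 721 had an unadjusted p under 0.05. For these windows limma took the spread almost wholly from its trend over all windows. The spread of a single window between 3 and 3 libraries therefore hardly enters its p-value. Windows of the same library are not independent either, so very small p-values of single windows can overstate their certainty. Risen windows held a median of 9 protein-coding genes and 19 tumour ATAC peaks, fallen windows a median of 1 gene and 0 ATAC peaks, and all windows a median of 5 genes and 6 ATAC peaks. No protein-coding gene was annotated in 118 of the 275 fallen windows. The counts rest on the scaling and on the length of the lists: 0 windows passed without scaling (576 with an unadjusted p under 0.05) and 0 passed with lists of equal length (219 with an unadjusted p under 0.05). Risen windows numbered 177, 32 and 14 without cKO replicates 1, 2 and 3 and 31, 50 and 45 without WT replicates 1, 2 and 3, fallen windows 307, 155 and 154 and 132, 228 and 265, and windows of 100 kb gave 4 and 27.

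The windows named here were chosen after their values were seen, by the smallest limma p among windows with a protein-coding gene. Passed over with 0 genes were the risen window on chromosome 19 from 35000001 to 36000000 (limma adjusted p = 0.000742) and fallen windows. The latter were chromosome 8 from 98000001 to 99000000 and chromosome 3 from 43000001 to 44000000. The named risen windows on chromosomes 3 and 2 hold 2 genes each, under the median of 5 of all windows. The strongest rise with genes was on chromosome 9, 66000001 to 67000000, a stretch of 15 genes that includes Herc1, Usp3 and Rab8b, where peaks covered 4.91% in cKO and 1.78% in WT, or 1.13 ± 0.258 and 0.474 ± 0.129 times the genome-wide coverage (limma adjusted p = 0.000255). The window on chromosome 3 from 52000001 to 53000000, which holds Foxo1, a transcription factor restrained by AKT signalling, and Cog6, was covered over 6.89% and 3.39% (1.55 ± 0.172 and 0.893 ± 0.1196 times, limma adjusted p = 0.000460). The window with Lypd6 and Mmadhc on chromosome 2 from 50000001 to 51000000 was covered over 3.54% and 1.13%. Among fallen windows, chromosome 1 from 117000001 to 118000000 was covered over 5.18% in cKO and 8.45% in WT (1.12 ± 0.305 and 2.22 ± 0.123 times, limma adjusted p = 2.81e-08). The window of the neuronal gene Slitrk5 on chromosome 14 from 111000001 to 112000000 was covered over 3.77% and 7.01%, and chromosome X from 126000001 to 127000000 over 5.80% and 8.81%.

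The same direction appeared when autosomal windows were grouped by gene number. Windows without a protein-coding gene were covered over 3.81 ± 1.22% in cKO and 4.39 ± 0.772% in WT (exact permutation p = 0.6), and windows with over 20 genes over 4.04 ± 0.589% and 2.91 ± 0.521% (exact permutation p = 0.2). The ratio of coverage in windows without a gene to that in all windows with 11 or more genes was 0.826 ± 0.210 in cKO and 1.31 ± 0.319 in WT, with no overlap between the groups (exact permutation p = 0.1, the smallest possible). The highest cKO ratio, 1.06, was near the lowest WT ratio, 1.10. The difference of -0.484 was -0.30 without WT replicate 1, whose ratio of 1.68 was the highest, and -0.247 with lists of equal length, where the exact permutation p was 0.7.

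**Figure D1:**
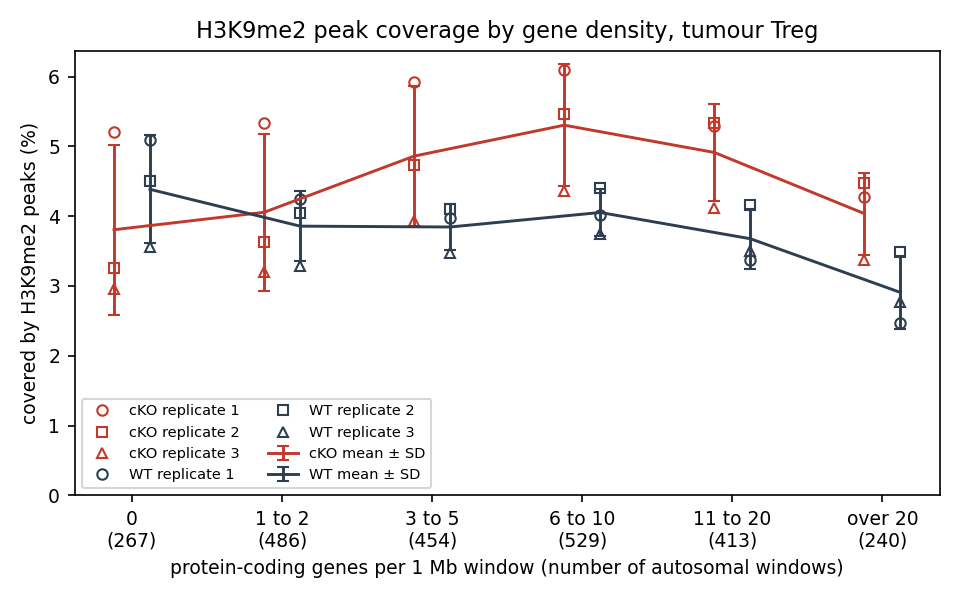
Percent of autosomal 1 Mb windows covered by H3K9me2 peaks (y axis) by the number of protein-coding genes per window (x axis, with the number of windows), for each of the 3 cKO and 3 WT libraries with the group mean ± SD. Mean coverage is 3.81% in cKO and 4.39% in WT where there is no gene, and 4.04% and 2.91% where there are over 20 genes.

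Chromosome X had the largest shift of any chromosome. Its coverage relative to all autosomes was 0.975 ± 0.0689 in cKO and 1.25 ± 0.0812 in WT, without overlap (exact permutation p = 0.1, the smallest possible), and 48 of its 163 windows fell while 0 rose. Fallen windows were most frequent in number on X, followed by chromosomes 1, 4, 3, 8 and 14 with 32, 22, 21, 21 and 20. Risen windows were most frequent on chromosome 9 with 11 and on chromosomes 2 and 5 with 10 each. The largest differences towards higher relative coverage were on chromosomes 19, 9 and 11, with 1.03 ± 0.0294, 0.989 ± 0.0308 and 0.890 ± 0.0538 in cKO and 0.918 ± 0.0286, 0.890 ± 0.0219 and 0.792 ± 0.0463 in WT. Gene number did not order the chromosomes throughout, since chromosome 7, with the most genes per Mb, had 1.04 ± 0.0158 in cKO and 1.07 ± 0.0122 in WT, with 3 risen and 18 fallen windows. Groups did not overlap for 6 chromosomes with higher and 6 with lower values in cKO of the 20, where chance gives 10%.

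**Figure D2:**
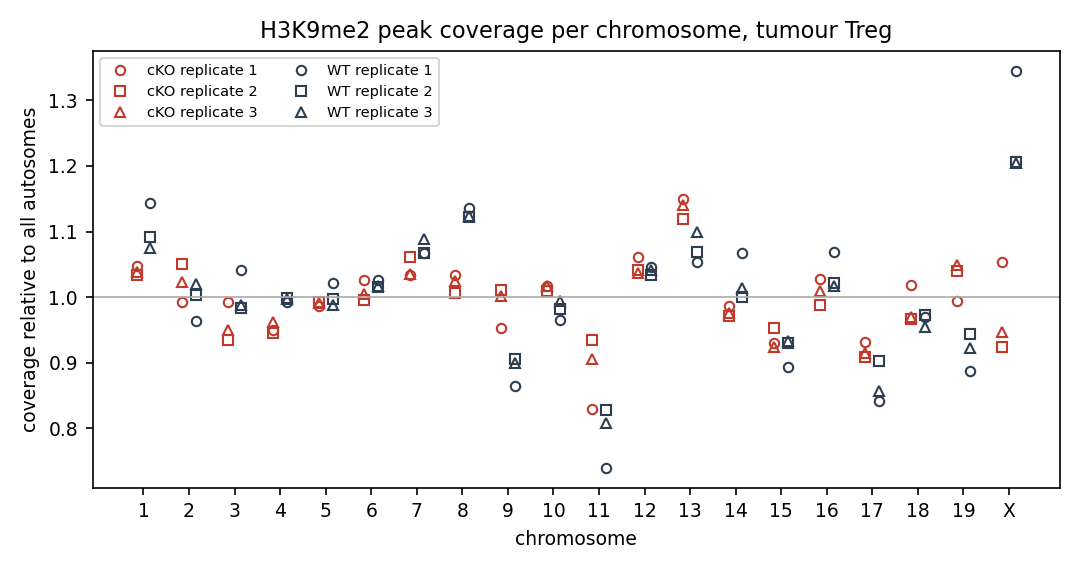
H3K9me2 peak coverage of each chromosome divided by the coverage of all autosomes (y axis) by chromosome (x axis), with a point for each of the 3 cKO and 3 WT libraries. On X the cKO libraries lie between 0.924 and 1.05 and the WT libraries between 1.204 and 1.345.

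**Figure D3:**
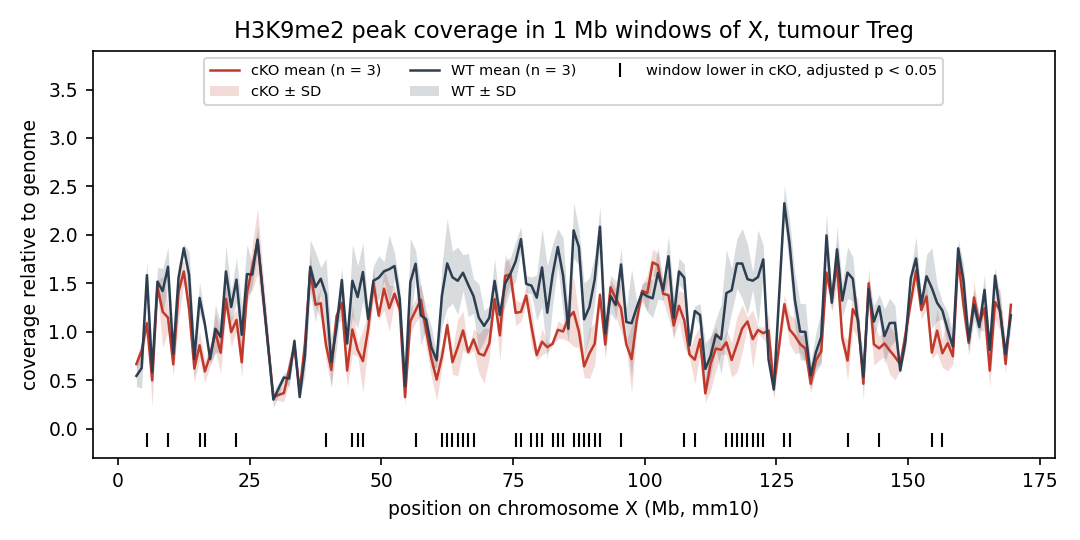
H3K9me2 peak coverage of 1 Mb windows divided by the genome-wide coverage of the library (y axis) along chromosome X in Mb (x axis), as the mean of 3 cKO and 3 WT libraries with bands of ± SD. Ticks mark the 48 of 163 windows that fell in cKO at a limma adjusted p under 0.05, a call lost without scaling and with lists of equal length.

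Several T cell genes lay in risen windows. Ctla4, an inhibitory receptor of Treg, and Icos, a costimulatory receptor, share the window on chromosome 1 from 60000001 to 61000000, which was covered over 6.07, 6.23 and 4.27% in cKO replicates 1 to 3 and 2.85, 2.60 and 2.401% in WT replicates 1 to 3 (1.23 ± 0.144 and 0.690 ± 0.0508 times the genome-wide coverage, limma adjusted p = 0.00499). Cd274 and Pdcd1lg2, which encode the PD-1 ligands, share a risen window on chromosome 19 from 29000001 to 30000000. It also holds Jak2 and Mlana, the risen member of the melanocyte list. That window had 1.49 ± 0.298 times the genome-wide coverage in cKO and 0.978 ± 0.184 times in WT (limma adjusted p = 0.00978). Risen windows held 4 of 19 Treg identity genes (Ctla4, Foxo1, Gpr83 and Izumo1r), 4 of 18 inhibitory receptor genes (Ctla4, Cd160, Cd274 and Pdcd1lg2), 4 of 24 tumour and effector Treg genes (Icos, Il10, Cxcr6 and Batf) and 4 of 23 PI3K-AKT-mTOR genes (Foxo1, Foxo3, Sgk1 and Rps6kb1), against about 4.77% of other genes. They held 3 of 23 JAK-STAT3 genes, 3 of 22 Th1 genes, 1 of 17 naive and lymphoid homing genes and 0 of 12 CD8 T and NK cell genes, and also 2 of 23 H3K9 methylation genes and 1 of 12 in each of the melanocyte, stromal and ubiquitous lists. For the 4 lists with 4 members each, Fisher's exact test gave adjusted p-values of 0.0510, 0.0510, 0.0771 and 0.0771, past no threshold, and genes that share a window are not independent. Fallen windows held 101 of 1101 olfactory receptor genes (9.17% against 2.09% of other genes, Fisher's exact test, adjusted p = 4.62e-30) and 42 of 346 vomeronasal receptor genes (12.1% against 2.30%, adjusted p = 1.11e-16), which lie in clusters and so count a few windows many times.

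Tumour and spleen Treg were compared by ATAC-seq with 1 library each, so the differences have no replicate check and no p-value is given. Tumour Treg had 27625 peaks and spleen Treg 13078. Most spleen peaks were also open in tumour Treg: 85.1% of them touched a tumour peak (Wilson 95% interval 84.5 to 85.7%, which covers counting error only), while 40.3% of tumour peaks touched a spleen peak (39.8 to 40.9%). With the tumour list shortened to its 13078 highest-scoring peaks, both shares were 66.5%. Tags in peaks made up 11.03% of the tumour and 4.77% of the spleen library, and the peak width set by the caller was 322 bp in tumour and 869 bp in spleen. A larger share of spleen peaks, 50.3% (49.5 to 51.2%), lay within 1 kb of an end of a protein-coding gene than of tumour peaks, 34.6% (34.1 to 35.2%). The distance was counted from the edges of a peak, so wider peaks reach farther. These shares were not repeated with lists of equal length. A peak near a gene end was found in both libraries for 7410 genes, in tumour alone for 2729 and in spleen alone for 274. With lists of equal length 7576 genes had a tumour peak near an end, against 7684 with a spleen peak. The spleen library also held 3 peaks on the short arm of Y and the tumour library 0.

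Among the fixed lists, genes of tumour and effector Treg had the largest surplus of tumour over spleen peaks, as deposited and with lists of equal length. Extended by 5 kb, they held 103 peaks in tumour and 29 in spleen, and 23 of 26 had a peak found in tumour alone, above all 10000 random lists of the same size. They were led by Rora, a nuclear receptor of tissue lymphocytes (19 and 2 peaks), Tnfrsf8, which encodes CD30 (9 and 1), Il1rl1, which encodes the interleukin-33 receptor ST2 (6 and 0), and Batf (6 and 2). Inhibitory receptor genes held 81 and 31 peaks, with Nfatc1 at 13 and 2, Lag3 at 6 and 1, Tox at 12 and 7 and Havcr2 at 4 and 0. Treg identity genes held 95 and 43, with Ikzf2, which encodes Helios, at 15 and 3, Runx1 at 14 and 6, Entpd1 at 9 and 3 and Nrp1 at 7 and 2. Th1 and interferon-gamma genes held 53 and 15, with Stat4 at 10 and 3 and Il18r1 at 6 and 0. JAK-STAT3 genes held 65 and 27, with Stat3 at 7 and 1, PI3K-AKT-mTOR genes 79 and 34, with Phlpp1 at 10 and 3, and H3K9 methylation genes 52 and 26, with Ehmt2 at 3 and 0. With lists of equal length the peaks were 54 and 29 for effector genes, 36 and 31 for inhibitory receptors, 50 and 43 for Treg identity, 27 and 15 for Th1, 39 and 27 for JAK-STAT3, 42 and 34 for PI3K-AKT-mTOR and 33 and 26 for H3K9 methylation. Among the single genes named here, Tox then had 3 tumour and 7 spleen peaks, Phlpp1 2 and 3 and Stat4 3 and 3. The other named genes still had more tumour peaks, from a clear surplus at Rora (11 and 2) to a slight one at Nfatc1 (3 and 2) and Runx1 (7 and 6). By the share of members with a peak found in tumour alone, these 7 lists and naive and lymphoid homing genes lay above the 95th percentile of random lists. Ubiquitous genes, at 22 and 15 peaks, lay at percentile 94.1 as deposited and at 99.8 with lists of equal length, so a high percentile was not limited to T cell genes.

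Naive and lymphoid homing genes held 70 tumour and 44 spleen peaks as deposited, and 22 and 44 with lists of equal length, so the direction turned. It turned in 5 of 14 lists, and the other 4 held few peaks. A peak found in spleen alone was present at 6 of 17 members as deposited and at 10 of 17 with lists of equal length, at percentiles of 99.985 and 100 among random lists. Treg identity genes showed the same, with 7 and 11 of 20 members at percentiles of 99.995 and 100. Inhibitory receptor, Th1 and JAK-STAT3 genes also lay above the 95th percentile both as deposited and with lists of equal length, and effector Treg and PI3K-AKT-mTOR genes only with the latter. Examples as deposited are Bach2, a repressor of effector differentiation (15 tumour and 11 spleen peaks, 2 of them in spleen alone), Foxp1 (14 and 11, 3 in spleen alone) and Bcl2 (9 and 4, 2 in spleen alone). Of the other fixed genes, Jmjd1c had 4 tumour and 2 spleen peaks, Pdcd1 3 and 1, Ifng 1 and 0, and Foxp3 2 and 2. The genes with the most peaks found in tumour alone were 147 to 735 kb long: Atxn1 with 21, Prkch, Rora, Runx2 and Tg with 17 each, Atg7 with 16, Itpr1 with 15, Rad51b and Septin9 with 14 and Prex1 with 13. Tiam1 had the most found in spleen alone with 6, followed by Immp2l with 5, Cacna1c, Map4k4, Pde4d and Ubac2 with 4, and Arhgap10, Arpp21 and Cfap20dc with 3.

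**Figure D4:**
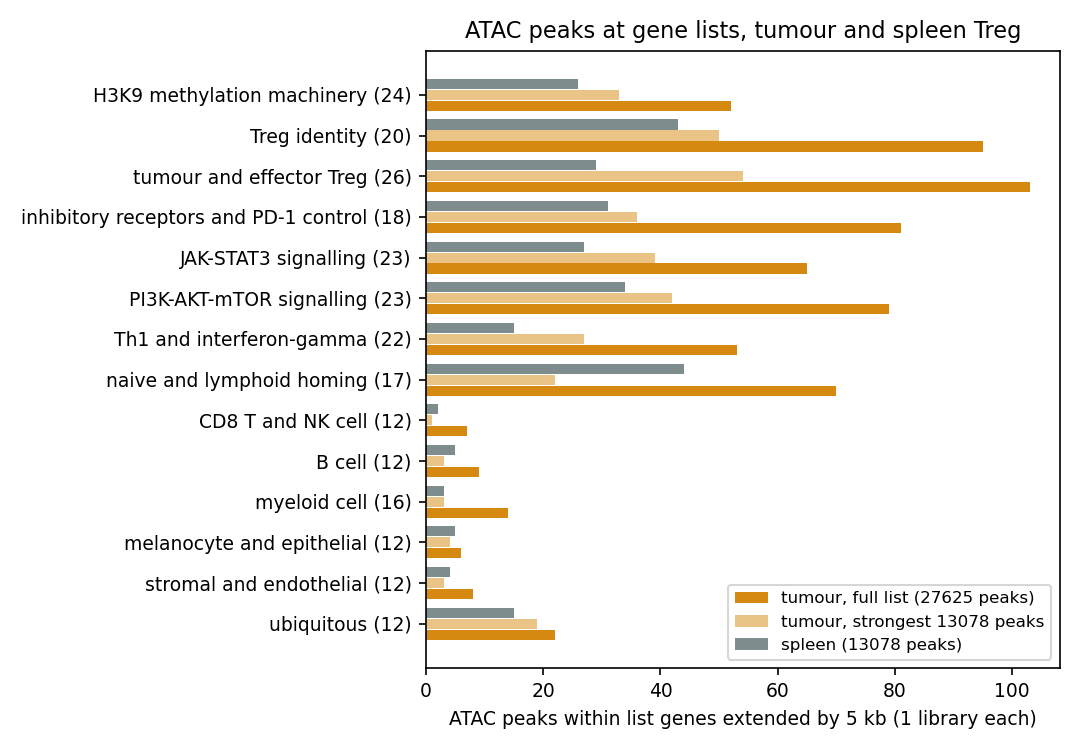
Number of ATAC peaks within the genes of each fixed list, extended by 5 kb (x axis), for the full tumour list of 27625 peaks, its strongest 13078 peaks and the spleen list of 13078 peaks, with 1 library each and the number of genes in brackets. Effector Treg genes hold 103, 54 and 29 peaks, and naive and lymphoid homing genes 70, 22 and 44.

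Accessible sites were set against the H3K9me2 peaks of tumour Treg. The centre of 6.26 ± 0.880% of tumour ATAC peaks lay in an H3K9me2 peak of the cKO libraries and of 5.49 ± 1.70% in those of the WT libraries (exact permutation p = 0.6). Relative to the share of the genome covered, this was 1.468 ± 0.25 and 1.502 ± 0.455 times (exact permutation p = 0.9). For spleen ATAC peaks the shares were 6.65 ± 0.700% and 6.10 ± 1.70% (exact permutation p = 0.9). The difference of 0.767 percentage points for tumour peaks turned to -0.613 with lists of equal length and to -0.141 without WT replicate 1, and that of 0.545 for spleen peaks turned to -0.879 and -0.407.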

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

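The checks in this part were chosen after the values had been seen, and these signals stand outside the main measurement.

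The list of cKO replicate 2 held a single peak on the mitochondrial chromosome, from position 151 to 6706, with a normalized tag count of 1314.9, and the other 7 libraries held 0. The spleen ATAC library held 3 peaks on the short arm of Y, at Uty, Eif2s3y and Ddx3y, where the tumour ATAC library held 0 although the density of its X peaks was enough for 7.77. Peaks on unplaced scaffolds made up to 0.214% of an H3K9me2 list and no less than 0.191%.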

How the results depend on the processing

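Chosen after the data were seen were all alternatives for 1 Mb windows, the X ratio and the gene-poor to gene-rich ratio, those of gene lists with equal lengths, higher scores, the gene span alone or a library left out, the other gene regions and the length-matched random lists. Covered length, number of peaks and both ratios kept their direction under every alternative run, with exact permutation p-values from 0.1 to 0.8. For genes, 0 passed under 15 of 16 alternatives and 1 on the arcsine square root scale. The cause of the changes below was not tested except where fewer peaks or libraries enter by construction.

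With lists of equal length, 1 Mb windows numbered 0 higher and 0 lower, gene lists 0 and 1 kb windows 926 in cKO alone, and the ATAC shares inside H3K9me2 turned to -0.613 (tumour) and -0.879 (spleen) percentage points. With the higher-scoring part of each list, 1 Mb windows numbered 51 and 125, 1 kb windows 631 and 503, and the 2 gene lists that passed were others, CD8 T and NK cell and zinc-finger genes, higher relative to other genes. An estimated correlation left 0 gene lists. Without scaling, 0 windows of 1 Mb were higher and 0 lower. Windows of 100 kb gave 4 and 27. Counting a 1 kb window as covered at any base gave 5567 and 3436, and windows of 5 kb gave 6 and 7. ATAC peaks shared were 39.3 and 83.0% (tumour and spleen) for an overlap of at least 50% of either peak, 66.5 and 66.5% with lists of equal length and 42.8 and 90.5% with higher-scoring peaks. Lists above the 95th percentile of random lists were 8 of 14 and 9 under each of 3 alternatives.

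Leaving out 1 library gave 14 to 177 higher and 132 to 307 lower 1 Mb windows, 0 to 2 gene lists (0 without cKO replicate 2 and without WT replicate 1), 1875 to 10213 and 1227 to 6670 windows of 1 kb, and -0.141 to 1.55 (tumour) and -0.407 to 1.22 (spleen) percentage points for ATAC peaks inside H3K9me2, both lowest without WT replicate 1.

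The replicate numbers share only a number. Correlations of same-numbered deviations were 0.0757, 0.00504 and 0.0260 over genes and 0.461, 0.190 and 0.0847 over 1 Mb windows, where cKO replicates 2 and 3 each correlated better with another WT number. With the replicate block, 0 genes and 2 gene lists passed and windows numbered 294 higher and 372 lower, or 405 and 99 without scaling. Windows of 2.5 or 10 kb around start sites were not run, since the gene table used gives no strand. Depth may limit single genes, as the median H3K9me2 peak rests on 8 to 9.5 tags, but this was not tested.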

Other observations

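The tests of this part were chosen after the results they bear on had been seen, except the comparison of X with autosomal windows of similar gene number, which was set before its result.

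In the ATAC libraries, lists for cells other than Treg held few peaks in either tissue. Myeloid genes held 14 tumour and 3 spleen peaks, B cell genes 9 and 5, CD8 T and NK cell genes 7 and 2, stromal and endothelial genes 8 and 4 and melanocyte and epithelial genes 6 and 5. Single genes that stood out were Pecam1, an adhesion molecule also found on leukocytes (7 and 1), Spi1, which encodes PU.1 (3 and 0), Gzmk (3 and 0) and Gzma (2 and 0). With lists of equal length the same lists held 3 and 3, 3 and 5, 1 and 2, 3 and 4 and 4 and 5 peaks. Pecam1 then had 3 tumour peaks and 1 spleen peak, Spi1 1 and 0, Gzmk 1 and 0 and Gzma 0 and 0.

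Correlations of coverage between libraries across 1 Mb windows, which are not independent, lay between 0.660 and 0.822 within cKO, 0.775 and 0.843 within WT and 0.331 and 0.724 between the groups. The ranges overlap because cKO replicate 1 correlated better with WT replicate 3 (0.724) than with cKO replicates 2 and 3 (0.660 and 0.717). Windows with 6 to 10 genes had 5.30 ± 0.877% in cKO and 4.05 ± 0.334% in WT (exact permutation p = 0.2). Chromosome 13 had 1 risen and 0 fallen windows of 117, and chromosome 8 had 1 risen and 21 fallen of 126.

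The shift of relative H3K9me2 coverage from gene-poor to gene-rich 1 Mb windows in cKO may be tied to the loss of Jmjd1c, which is a hypothesis from these data. The share of tags in the peaks counted by the headers was similar, 32.7 ± 2.89% in cKO and 33.3 ± 1.45% in WT (exact permutation p = 0.9). Adjusted for it, the gene-poor to gene-rich ratio differed by -0.535 (SE 0.1798), against -0.484 before. The slope came from 6 libraries. As the header share hardly differed between the groups, the adjustment could move the ratio only a little, so no conclusion is drawn from it. The deposited lists hold 24.4 to 43.9% of the peaks counted by the headers, and the share of tags in the deposited peaks is not known. The longer lists of cKO stay open: with lists of equal length the contrast between risen and fallen windows differed by 0.890, against 1.05 as deposited, and the groups overlapped (exact permutation p = 0.2). Separate preparation of cKO and WT cannot be told apart from genotype, because 0 prefixes of the sample names in the file headers were shared between the groups. GC content and mappability of the windows were not tested, since no genome sequence was at hand. Of the 10 splits of the 6 libraries, 1, the real split, gave 372 windows and the highest other gave 0, but 10 splits are too few for a share under 0.05.

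With the lists as deposited, broad classes of gene number did not account for the lower relative coverage of X in cKO. Against autosomal windows weighted to the same classes (0, 1 to 2, 3 to 5, 6 to 10, 11 to 20 and over 20 genes), X still differed by -0.258. Its ratio was 0.971 ± 0.0513 in cKO and 1.23 ± 0.0604 in WT (exact permutation p = 0.1, the smallest possible). This comparison was not run with lists of equal length. Male mice among the cKO samples and female mice among the WT samples stay open. On the short arm of Y, cKO replicate 2 held 1 H3K9me2 peak, 0.0102 of the number that 50% of its X density would give. The other cKO libraries and all WT libraries held 0. No library therefore shows that peaks of the mark form there at such a density. With lists of equal length the X ratio differed by -0.194 and the groups overlapped (exact permutation p = 0.2), so the longer lists of cKO stay open. The caller's filter on local enrichment, the separate preparation and the genotype were not tested further, and GC content and mappability were not tested. A chromosome-wide change of the mark is therefore a hypothesis only.

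The larger number of ATAC peaks in tumour Treg may come in part from a library with more tags in peaks and narrower peaks. With lists of equal length 8 of 14 gene lists still had more tumour than spleen peaks, 5 had fewer and 1 had equal numbers, against 14 of 14 as deposited. With 1 library each, tissue and library quality cannot be told apart, and the Y peaks found in spleen alone leave a difference in the sex of the donors open as well.

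For the number of genes passing, the splits say nothing: the real split gave 0, so all 10 splits had to give as many, and the highest other was 0. At an unadjusted limma p under 0.05 the real split gave 1591 genes and the highest other 1084. After division by genome-wide coverage these were 1273 and 1098. Again 10 splits are too few for a share under 0.05. For separated 1 kb windows the splits were too few for a share under 0.05, as 1 of 10 gave as many as the real 2515, with a highest other of 2283.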
